A study of Rattus norvegicus with 10 samples.

How the data were processed

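The series profiled N6-methyladenosine (m6A), a methyl mark on adenosines of RNA, in primary cardiomyocytes isolated from newborn rats. The method was m6A RNA immunoprecipitation followed by sequencing (MeRIP-seq): RNA is pulled down with an antibody against m6A, sequenced, and places where reads pile up above a control are called as peaks. Per the labels, 10 libraries fall into 5 groups of 2: input RNA and m6A immunoprecipitates (IP) of hypertrophic cells, input RNA and m6A IP of quiescent cells, and IP with normal IgG, which does not recognise m6A. Hypertrophic cells were cultured with 2% bovine serum and quiescent cells without serum. The IgG libraries came from hypertrophic cells, per the labels.

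The authors' processing is known only in outline. CASAVA 1.8, TopHat, MACS 1.4 and the rat build rn4 are named in the submitters' processing notes, without parameters. The deposited files are 1 peak list and 1 matching summit list per condition, each called against the negative control, per the names of the deposited lists. The list for normal cells is that of the quiescent cells, per the labels. Whether the 2 IP replicates of a condition were pooled, or a list and its summit heights rest on 1 of them, is not given in the sources used here. The deposited peak score has the layout of the MACS 1.4 BED output, in which it is a fixed multiple of minus the log10 of the peak's p-value; all deposited peaks score 50 or more. The deposited summit files hold a signal, the height of the read pileup at the peak's highest base, in whole numbers, with no scaling stated. The largest height was 164 in both lists, and 817 hypertrophic and 699 quiescent peaks lay close to it. Heights may therefore have a ceiling that compresses tall summits. The input libraries are not analysed here. Read totals were not given in the sources used here, so the depth behind each peak is unknown beyond its summit height.

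Because each condition is represented by 1 list, there was no spread between replicates to test against. Intervals and p-values below describe these lists, not the variation between cultures. Scores rank and filter peaks within a list. Where median scores, score bins or a score threshold are set side by side for the lists, the same score was used in both, and such values depend on the score scales being comparable, which was not tested. Coordinates are in rn4, as the files give them, counted from 1. The files carry no gene names, and the gene table at hand belongs to another rat assembly (GRCr8), so peaks are named by position. The planned comparisons by gene, gene region, gene list and sequence motif (DRACH, the usual m6A sequence context) were not made for that reason. All deposited columns of values belong to the listed groups, and 0 were left out.

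A peak was called shared when it overlapped a peak of the other list by at least 1 bp (bedtools 2.31.1), and condition-only otherwise. Chance overlap was taken from 100 random shifts of the other list along each chromosome, wrapping at the last peak end, since chromosome lengths were not used. Scores of shared and condition-only peaks were compared within a list by a two-sided permutation test of the difference in medians with 100000 resamples. Shares carry Wilson 95% intervals, which cover counting error only. Ratios and some shares carry 95% intervals from 1000 bootstrap draws of 1 Mb blocks of the genome, which allow for neighbouring peaks moving together. Summit heights of condition-only peaks were divided by the median of shared peaks of the same list in the same class of score and width. Peak numbers per 1 Mb window were compared by a two-sided exact binomial test against the split of the whole lists, with Benjamini-Hochberg adjustment over the windows. That test treats shared sites as independent peaks, which makes it conservative, so it was also run on condition-only peaks. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

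The peaks named in the text were fixed by rule before the data were examined: the 10 highest scores in each list and the 10 highest scores among the condition-only peaks of each list, with ties broken by width. The overlap rule, the chance shifts, the score comparison and their alternatives were also fixed at that point. The score bins, the bootstrap intervals, the threshold of 200 for strong peaks, the summit height comparison, the chromosome comparison and the window scan were chosen after seeing the data. Blocks of 50 kb had been looked at before the windows of 1 Mb. The code was tested on simulated lists made from the hypertrophic list. An overlap share of 69.88% was recovered as 69.95% over 65539 peaks. The window scan found 20 of 20 windows in which most peaks of 1 list had been removed, with 0 other windows called among 2706. That scan set the hypertrophic list against a thinned copy of itself, so untouched windows held equal counts and could not be called. The thinned windows were drawn from those with many peaks. It checked the code, and not the rate of false calls or the power in windows of usual size. A permutation test on random labels gave p under 0.05 in 2 of 40 runs.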

Results

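The deposited data describe where m6A peaks lie on the rat genome in hypertrophic and in quiescent neonatal cardiomyocytes. The hypertrophic list held 65539 peaks and the quiescent list 68440. Each was called by the authors against the same IgG control, which came from hypertrophic cells. There are 2 m6A IP libraries but 1 list for each condition, which may rest on both libraries or on 1, so no value below has a replicate error. The lists covered chromosomes 1 to 20 and X.

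m6A peaks were numerous and short in both conditions. The median peak width was 340 bp in hypertrophic cells, with quartiles of 240 and 524 bp, and 342 bp in quiescent cells, with quartiles of 240 and 535 bp. Peaks covered 29.9 Mb in the hypertrophic list and 31.5 Mb in the quiescent list. The quiescent list held 1.04 times as many peaks (block bootstrap interval 1.03 to 1.05) and 1.05 times the covered length. The median peak score was 119.8 in the hypertrophic list and 126.5 in the quiescent list, and the median summit height was 18 and 16 respectively. Scores ran from 50 to 3233 in the hypertrophic list and from 50 to 3225 in the quiescent list. Exactly 3100 was the score of 462 hypertrophic and 603 quiescent peaks, and 55 and 45 peaks scored higher. So many peaks at 1 value point to a cap, so peaks at 3100 cannot be ranked against each other or against the few above it.

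Peak density differed several-fold between chromosomes, and the chromosomes ranked alike at both ends of the range in the 2 conditions. Chromosome 12 was the densest, with 43.9 peaks per Mb of spanned sequence in hypertrophic and 46.5 in quiescent cells. Chromosome X was the sparsest, with 11.6 and 11.8 peaks per Mb. Chromosomes 16 and 17 had the highest ratios of quiescent to hypertrophic peaks. On chromosome 16 there were 2679 quiescent against 2380 hypertrophic peaks, a ratio of 1.13 (block bootstrap interval 1.05 to 1.21). On chromosome 17 there were 2931 against 2647 peaks, a ratio of 1.11 (interval 1.05 to 1.17). Chromosome 10 was the only one with fewer quiescent than hypertrophic peaks, 3597 against 3605, a ratio of 0.998 whose interval of 0.968 to 1.03 includes equal numbers.

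**Figure D1:**
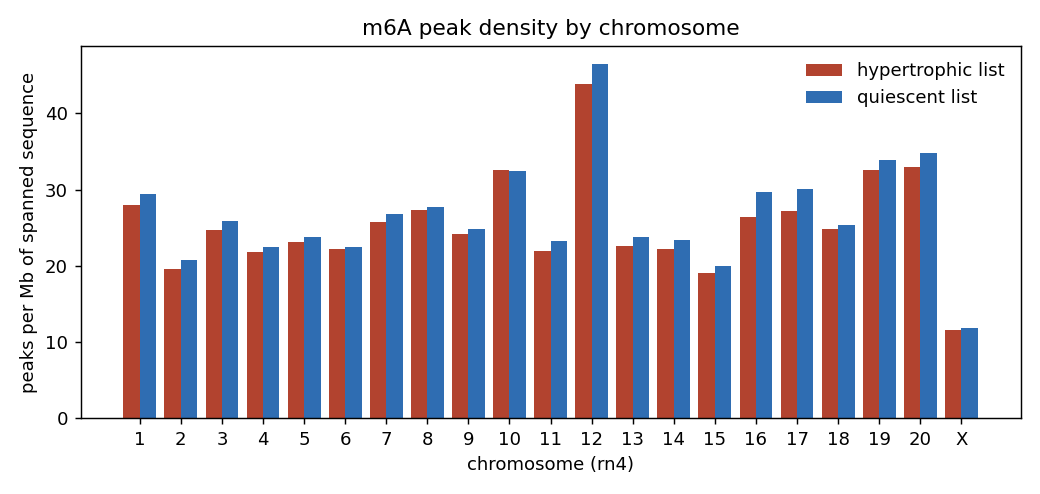
Peaks per Mb of spanned sequence (vertical axis) on each rn4 chromosome (horizontal axis) in the hypertrophic and the quiescent list; each bar is 1 deposited list, without replicate error. Chromosome 12 reaches 43.9 and 46.5 peaks per Mb and chromosome X stays at 11.6 and 11.8.

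Nearly all peaks with scores of 1600 or more were found in both conditions (99.9% in the hypertrophic and 99.8% in the quiescent list). All 10 of the highest-scoring hypertrophic peaks overlapped a quiescent peak, and all 10 of the highest-scoring quiescent peaks overlapped a hypertrophic one. These 20 lie among the few scores above 3100 and are not ranked over the peaks at 3100. The highest listed hypertrophic score, 3233, belonged to a peak on chromosome 2 from 62154210 to 62155253, whose quiescent partner scored 3100. A peak on chromosome 1 from 89853349 to 89854286 scored 3230, with a quiescent partner at 1901. One on chromosome 20 from 43659287 to 43659902 had its summit 4 bp from the nearest quiescent summit. In the quiescent list, the highest listed score of 3225 was that of a peak on chromosome 6 from 27277925 to 27279304, with its summit 9 bp from the nearest hypertrophic summit. A quiescent peak of 3936 bp on chromosome 8 from 72327216 to 72331151 scored 3221 and overlapped 6 separate hypertrophic peaks, of which the highest scored 844.

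The comparison the design implies is between serum-stimulated, hypertrophic cells and serum-free, quiescent cells. Most peaks were common to both. Of the hypertrophic peaks, 48600 (74.2%, Wilson interval 73.8 to 74.5%) overlapped a quiescent peak, and 16939 did not. Of the quiescent peaks, 48585 (71.0%, interval 70.6 to 71.3%) overlapped a hypertrophic peak, and 19855 did not. When the lists were joined, 47655 of 84446 regions (56.4%) held peaks of both conditions. Shared peaks lay at closely matching positions: the median distance between their summits was 14 bp, with quartiles of 4 and 42 bp, and 87.9% of shared hypertrophic peaks had a quiescent summit within 100 bp.

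The overlap was far above that of randomly shifted lists. Shifted quiescent lists touched 2.33% ± 0.074 (SD over 100 shifts) of the hypertrophic peaks, and shifted hypertrophic lists touched 2.23% ± 0.069 of the quiescent peaks. With shifts of only 5 to 50 kb, which keep the lists near the same loci, the shares were 4.47% ± 0.405 and 4.40% ± 0.481. None of the 100 shifts of either kind reached the observed share in either direction (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). Shifts of either kind can move peaks off transcribed sequence, where peaks of RNA must lie. The test therefore does not separate shared m6A sites from RNA that is merely expressed in both conditions. Both lists were called against the same IgG libraries, so part of the overlap may come from that shared control, and its size could not be simulated without the libraries.

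Condition-only peaks were concentrated among the weakest peaks. In the hypertrophic list, shared peaks had a median score of 159.8 and hypertrophic-only peaks one of 69.98, a difference of 89.8 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). In the quiescent list the medians were 173.5 and 76.3, a difference of 97.2 with the same permutation p of 1e-05. Both lists stop at a score of 50, so a peak loses its partner when its site scores below that in the other list. Shared peaks were also wider, with medians of 380 against 259 bp (hypertrophic) and 388 against 264 bp (quiescent), which makes overlap easier. The cut and overlap rule favour higher scores in shared peaks, and the test cannot separate this from weak sites specific to a condition. Of peaks scoring from 50 to 60, 41.5% were shared in the hypertrophic list and 38.5% in the quiescent list. From 200 to 400, the shares were 96.3% (Wilson interval 95.9 to 96.7%) and 88.7% (interval 88.1 to 89.3%). At 1600 and above, 1674 of 1676 hypertrophic peaks and 2080 of 2085 quiescent peaks were shared. Condition-only peaks made up 25.8% of the hypertrophic peaks and 18.2% of their covered length, against 29.0% and 20.9% in the quiescent list.

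**Figure D2:**
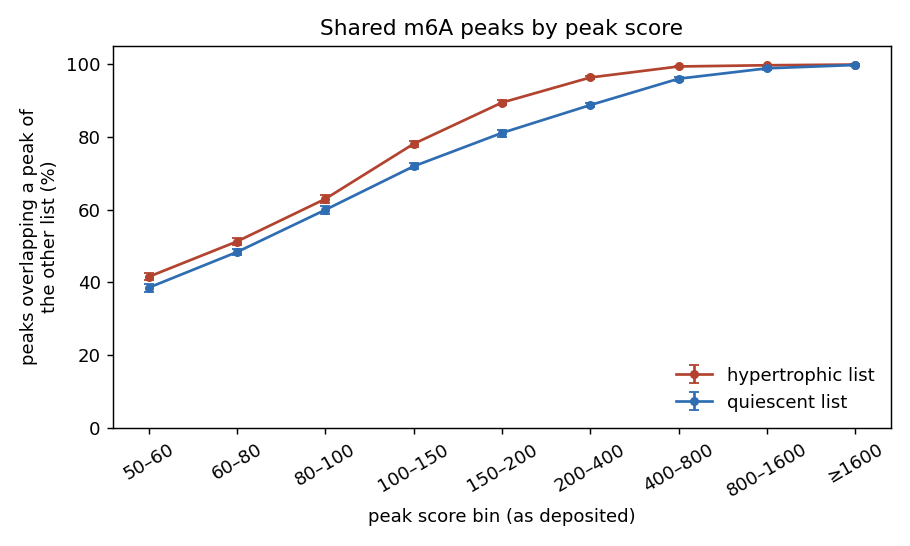
Percentage of peaks that overlap a peak of the other list by at least 1 bp (vertical axis) in bins of the deposited peak score (horizontal axis), with Wilson 95% intervals, for the hypertrophic and the quiescent list. The share rises from 41.5% and 38.5% in the lowest bin to 99.9% and 99.8% at scores of 1600 or more, and the quiescent list lies lower from 200 to 400 (88.7% against 96.3%).

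Condition-only peaks with strong scores were uncommon, and more of them were quiescent than hypertrophic. With a score of at least 200, 423 of 20458 hypertrophic peaks (2.07%, block bootstrap interval 1.86 to 2.27%) had no quiescent partner, and 1561 of 23346 quiescent peaks (6.69%, interval 6.32 to 7.03%) had no hypertrophic partner. The ratio of the 2 counts was 3.69 (interval 3.26 to 4.16), while all condition-only peaks stood at a ratio of 1.17 (interval 1.13 to 1.21) and all peaks of that score at 1.14 (interval 1.12 to 1.16). The ratio takes a score to mean the same in both lists, and it depended on the rule: it was 2.77 among the 20000 highest scores of each list, 1.65 with scores of at least 100, 6.60 with scores of at least 400 and 1.57 when shared peaks had to have summits within 100 bp. By summit height the order of the counts was the other way: above 45 there were 1345 hypertrophic-only and 1211 quiescent-only peaks. Shared peaks of that height numbered 12325 in the hypertrophic and 10680 in the quiescent list. The hypertrophic list thus held more tall peaks of both kinds, and the counts do not show a larger condition-only share. That cut was chosen after the data were seen, and the scaling of heights is not stated. The IgG control came from hypertrophic cells only, for both lists.

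Among the hypertrophic-only peaks, 2 scored 3100 or more and cannot be ranked against each other. One lay on chromosome 10 from 110712852 to 110714019, with a score of 3188, a summit height of 53 and 35148 bp to the nearest quiescent peak. The other was a broad peak of 12859 bp on chromosome 15 from 40331725 to 40344583, with a score of exactly 3100 and a summit height of 136. The third, on chromosome 4 from 135453535 to 135454476, scored 1296. The fourth, on chromosome 3 from 42436768 to 42437295, scored 1141 but lay 135 bp from a quiescent peak. The remaining 6 lay on chromosomes 9, 19, 15, 6, 1 and 2, and the 10 peaks scored from 1019 to 3188.

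The highest-scoring quiescent-only peak lay on chromosome 15 from 59343565 to 59345168, with a score of 2707, a summit height of 29 and 87363 bp to the nearest hypertrophic peak. A peak on chromosome 4 from 4632120 to 4634494 followed, with a score of 2358 and a height of 21. A peak of 5537 bp on chromosome 12 from 28500847 to 28506383 scored 2349, and one on chromosome 13 from 109345511 to 109346972 scored 1816. The fifth, on chromosome 1 from 186319611 to 186321655, scored 1616, and the sixth, on the same chromosome from 42199273 to 42205356, scored 1523 and lay 424 bp from a hypertrophic peak. The other 4 lay on chromosomes 6, 19, 4 and 18, and the 10 peaks scored from 1255 to 2707. Their median summit height was 41.5, against 85 for the 10 hypertrophic-only peaks.

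Strong quiescent-only peaks had lower pileups than shared peaks of the same score, while no such difference was detectable for hypertrophic-only peaks. From a score of 200 to 300, the median summit height was 14 for 912 quiescent-only peaks and 21 for 6165 shared quiescent peaks. In the hypertrophic list both medians were 25, over 312 and 6328 peaks. From 400 to 600, the medians were 18 and 31 in the quiescent list and 52.5 and 39 in the hypertrophic list. After matching on score and width, over scores from 200 to below 3100, quiescent-only peaks had a median log2 height ratio to shared peaks of -0.52 (block bootstrap interval -0.55 to -0.50, 1561 peaks), and hypertrophic-only peaks one of 0 (interval -0.13 to 0.06, 421 peaks); the intervals do not overlap.

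**Figure D3:**
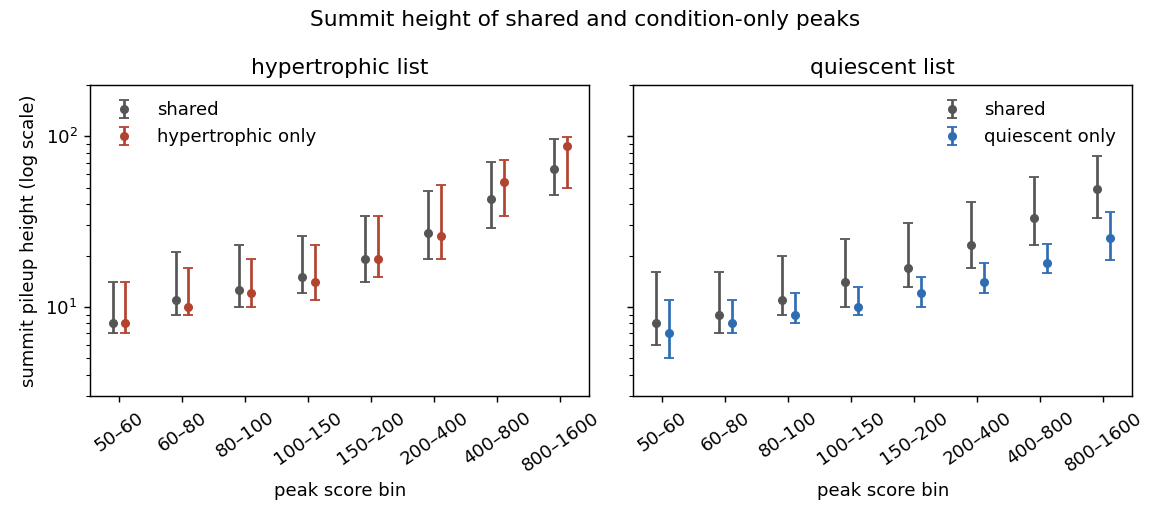
Median summit pileup height with quartiles (vertical log axis) by bin of the deposited peak score (horizontal axis), for shared and condition-only peaks of the hypertrophic list (left) and the quiescent list (right). Quiescent-only peaks lie below shared peaks from 200 to 400 (14 against 23) and from 400 to 800 (18 against 33). Hypertrophic-only peaks stand beside theirs from 200 to 400 (26 against 27). From 400 to 800 they lie above theirs (54 against 43), on only 37 hypertrophic-only peaks.

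Along the genome, condition-only peaks of either list were spread unevenly, and the windows with the lowest p for total peak number lay on chromosomes 16 and 17, with more quiescent peaks. The genome was divided into 2727 windows of 1 Mb with at least 1 peak, which held a median of 21 hypertrophic and 23 quiescent peaks. The window on chromosome 17 from 67000001 to 68000000 held 20 hypertrophic and 66 quiescent peaks, a ratio of 3.30 (exact interval 1.98 to 5.75; exact binomial p = 1.3e-06, adjusted p = 0.0035). The window on chromosome 16 from 27000001 to 28000000 held 95 and 175 peaks, a ratio of 1.84 (exact interval 1.43 to 2.39; exact binomial p = 6e-06, adjusted p = 0.0081). Of these, 49 and 87 were quiescent-only peaks. Summed over both lists the chromosome 16 window held the most peaks, but in the hypertrophic list alone others held more, such as chromosome 17 from 8000001 to 9000000 with 121 hypertrophic and 129 quiescent peaks. In the opposite direction, chromosome 7 from 27000001 to 28000000 held 51 hypertrophic and 27 quiescent peaks (exact binomial p = 0.0044, adjusted p = 1). No other window passed, but this test takes the peaks of the lists as independent although most are shared sites: 43 windows had an exact binomial p under 0.05, against 104.4 expected under that model. With condition-only peaks alone, a test chosen after the data were seen, 53 of 2704 windows passed, 29 of them with relatively more quiescent-only peaks. Among them, picked after their values were seen, chromosome 16 from 27000001 had 6 hypertrophic-only and 87 quiescent-only peaks, chromosome 17 from 67000001 had 3 and 49, and chromosome 1 from 52000001 had 0 and 34. In the opposite direction, chromosome 1 from 193000001 had 26 hypertrophic-only and 3 quiescent-only peaks, and chromosome 5 from 148000001 had 22 and 2. Neighbouring condition-only peaks are not independent, so the p-values behind these 53 calls are too small. For all peaks the same dependence works against the conservative effect of shared sites, and their balance in a given window is unknown. In the test on all peaks, neither window passed with peaks within 1000 bp joined, only chromosome 16 passed with scores of at least 100, and the chromosome 16 region from 27000001 did not pass with windows moved by 0.5 Mb or of 0.5 Mb.

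**Figure D4:**
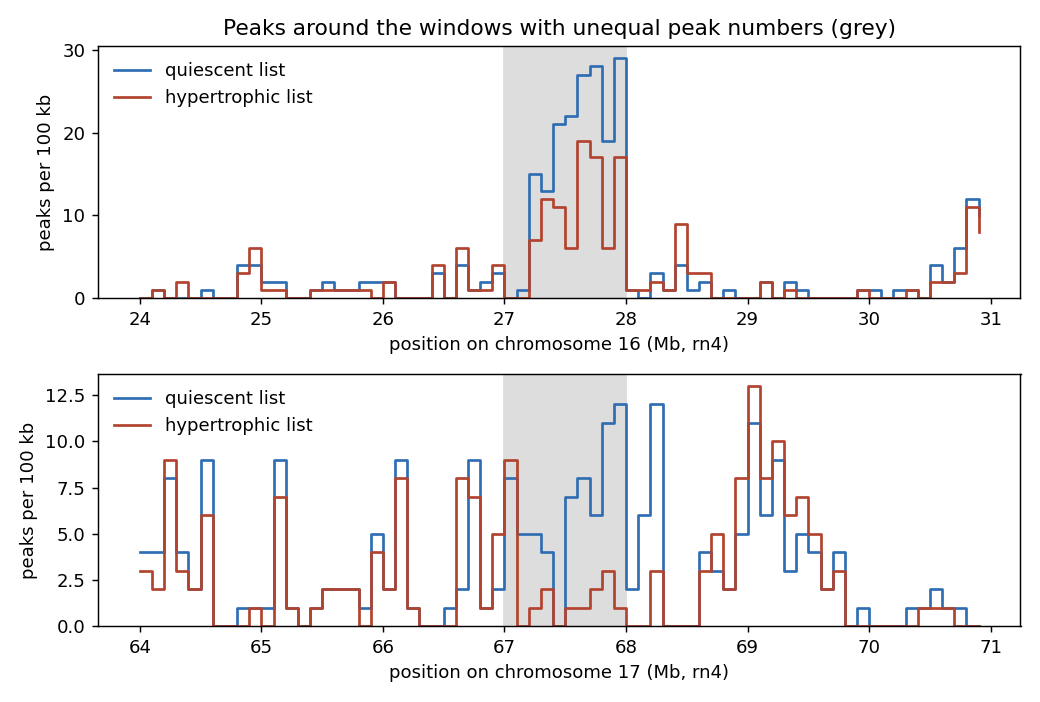
Number of peak summits per 100 kb (vertical axis) along 7 Mb of chromosome 16 (top) and chromosome 17 (bottom), in rn4 coordinates in Mb (horizontal axis), for the quiescent and the hypertrophic list; the grey bands mark the 1 Mb windows. The quiescent list lies above the hypertrophic list in 9 and 8 of the 10 bins inside the bands, with 175 against 95 and 66 against 20 peaks in all.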

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

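In this part, the test on the 20000 highest scores was added after the ratio of 3.69 was seen but before its own result was; the tests on summit height, on pileup at shared sites and on the windows were chosen only after the results were seen, and the score bound of 100 and a p bound of 0.05 shared over the 2 windows replaced earlier choices in the window tests once values had been seen.

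Quiescent-only peaks with a score of at least 200 outnumbered hypertrophic-only peaks of that score 3.69-fold, with a block bootstrap interval of 3.26 to 4.16 that lies above the 1.14 of all peaks of that score; the interval covers variation along the genome, not between cultures. Matching the counted peaks by rank lowered the ratio but did not remove the excess. Among the 20000 highest scores of each list the ratio was 2.77 (interval 2.44 to 3.14). Partners were sought in the whole other list, down to its lowest score of 50. A quiescent list that simply reaches higher scores is therefore not excluded, because its peaks could lack hypertrophic partners that fell below that floor. At shared peaks with summits within 100 bp the quiescent pileup was lower, with a median log2 ratio of -0.16 (interval -0.17 to -0.15). If summit heights are unscaled pileups, a deeper quiescent IP of equal enrichment would have made it higher. A deeper but less enriched quiescent IP is not excluded, because pileup at these sites mixes depth with enrichment and read totals are unknown. A candidate explanation is that the IgG control was taken from hypertrophic cells only, so that a site in RNA scarce in those cells could meet few control reads and score high on a small pileup; the matched height ratio of -0.52 for quiescent-only peaks, against 0 for hypertrophic-only peaks, is consistent with it. A real gain of methylation or of transcripts in quiescent cells stays open, because the series lists no IgG library from quiescent cells and the input libraries were not analysed here.

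On chromosome 16, the window from 27000001 to 28000000 held 1.84 times as many quiescent as hypertrophic peaks, which differs from the lists as a whole by the exact binomial test on all peaks; on condition-only peaks 53 windows passed, so it is not alone. The excess was not confined to peaks near the calling threshold. The ratio was 2.19 (exact interval 1.57 to 3.10) with scores of at least 100, against 1.08 for the lists, and 2.76 with the bound of 200 tried first. These are some of the same peaks, and the bound was put on both lists. Higher quiescent scores in this window (median 153.7 against 110.25), with hypertrophic partners below the bound, are therefore not excluded. A single locus of under 200 kb is argued against, since 9 of the 10 bins of 100 kb held more quiescent peaks. After joining peaks within 1000 bp the ratio was 1.395 (interval 1.04 to 1.88, 113 against 81 peaks), and a broad signal split into more peaks cannot be told apart from more sites, because the exact binomial p of 0.044 missed a bound of 0.05 shared over the 2 windows, which was set after it was seen. A longer transcription unit, or a difference between the conditions in transcription or methylation, may contribute and was not tested.

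On chromosome 17, the window from 67000001 to 68000000 held 3.30 times as many quiescent as hypertrophic peaks, which differs in the same way. With scores of at least 100 the ratio was 6.75 (exact interval 2.35 to 26.5, 27 against 4 peaks), but with the bound of 200 tried first it was 2.25 on 9 against 4 peaks (exact binomial p = 0.28), so peaks near the threshold cannot be told apart from other causes here, because the few strong peaks decide nothing and the bound of 100 was chosen after that value was seen. Joining peaks within 1000 bp left 49 quiescent and 20 hypertrophic peaks, a ratio of 2.45 (interval 1.43 to 4.35, exact binomial p = 0.001). Separate counting of neighbours thus made up part of the excess, and the remaining ratio argues against it as the whole cause. The p bound for that was set after the values were seen, and the joined window no longer passed the scan of all windows. More quiescent peaks in 8 of the 10 bins of 100 kb argue against a single locus of under 200 kb. A longer transcription unit, or a difference between the conditions, may contribute and was not tested.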

How the results depend on the processing

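The alternatives on windows and on the ratio of strong condition-only peaks were chosen only after the window calls and the ratio of 3.69 were seen; for the 20000 highest scores, the expected outcome was written before its own value was seen. No paired analysis was possible because each condition has 1 peak list and no values per replicate, and for the same reason no replicate could be left out. The results by gene, gene region, gene list and motif, with their alternatives, were not run. Scores of at least 100 left 38392 hypertrophic and 41281 quiescent peaks; scores of at least 200 left 20458 and 23346, covering 14.4 and 16.2 Mb. The shared percentage (hypertrophic, then quiescent) was 69.4 and 66.5 with 50% reciprocal overlap, 65.2 and 62.4 with summits within 100 bp, 76.4 and 73.5 with peaks within 500 bp, and 90.5 and 85.4 for peaks scoring at least 100 against the whole other list. With that score in both lists the hypertrophic share was 76.2, and among the 5000 highest scores of each list 70.98 (in the quiescent list both stayed within the interval). Local shifts of 5 to 50 kb gave chance shares of 4.47 and 4.40. The excess in score of shared peaks was 81.3 and 82.6 with summits within 100 bp, where the same lower score limit of the lists applies. The files hold no random or unplaced sequences, so leaving these out removed no peak. Of the 20 named condition-only peaks, 2 had a partner within 500 bp. The number of windows called went from 2 to 1 with scores of at least 100 (chromosome 16) and to 1 with windows of 0.5 Mb (chromosome 17). It fell to 0 with peaks within 1000 bp joined. There, 22 windows had an unadjusted exact binomial p under 0.05, against 103.7 expected for independent peaks. The number called rose to 53 with condition-only peaks. In that setting 313 windows had an unadjusted exact binomial p under 0.05, against 82.5 expected for independent peaks. With windows moved by 0.5 Mb, 2 were called, on chromosome 17 with 11 hypertrophic and 64 quiescent peaks and on chromosome 16, from 37500001, with 1 and 23. The ratio of strong condition-only peaks ranged from 1.57 to 6.60 over its alternatives. With scores of at least 200 the chromosome 17 ratio was 2.25 (exact binomial p = 0.28, 4 against 9 peaks), too few to tell. The depth of the libraries is unknown, and near the score threshold a missing partner need not be a missing site.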

Other observations

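In this part, the test on peaks with none of the other list within 50 kb was set before its result was seen; the comparisons by gap, by blocks of 50 kb and by tall summits were chosen only after the data were seen. Many condition-only peaks lay near peaks of the other condition. No baseline from random positions was made, so whether they lay nearer than by chance was not tested. Of the hypertrophic-only peaks, 41.5% lay within 5 kb of a quiescent peak, and 7.46% (block bootstrap interval 6.92 to 8.03%) had none within 50 kb. Of the quiescent-only peaks, 36.4% lay within 5 kb of a hypertrophic peak, and 15.7% (interval 14.9 to 16.6%) had none within 50 kb. The median gap was 7.05 kb for hypertrophic-only and 9.74 kb for quiescent-only peaks. A block of 50 kb on chromosome 16 from 37850001 to 37900000 held 16 quiescent and 0 hypertrophic peaks (exact binomial p = 3.2e-05, adjusted p = 1 over all blocks of that size). The hypertrophic counterpart with the lowest p was chromosome 4 from 64750001 to 64800000, with 7 hypertrophic and 0 quiescent peaks (exact binomial p = 0.0067, adjusted p = 1).

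A hypothesis is that many strong quiescent-only peaks belong to transcripts with no peak in the other condition, rather than to extra sites on transcripts marked in both. Among peaks scoring at least 200, 265 of 1561 quiescent-only peaks (16.98%) and 21 of 423 hypertrophic-only peaks (4.96%) had no peak of the other list within 50 kb, a difference of 12.0 percentage points (block bootstrap interval 9.34 to 14.9). This is consistent with the hypothesis for that part of the quiescent-only peaks. It does not separate a silent transcript from an unmethylated one, and most strong quiescent-only peaks did lie within 50 kb of a hypertrophic peak. Nor does it separate them from the IgG control of hypertrophic cells only, which could also raise scores in RNA scarce there. The share was similar among all quiescent-only peaks (15.7%) and was 7.46% among all hypertrophic-only peaks. Isolation was therefore not particular to the strong quiescent-only peaks.

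Tall condition-only peaks scored low. With a summit height above 45, the median score was 85.1 for 1345 hypertrophic-only peaks, against 422.8 for shared ones, and 80.6 for 1211 quiescent-only peaks, against 457.7. Low scores were not particular to tall peaks, since condition-only peaks of all heights had medians of 69.98 (hypertrophic) and 76.3 (quiescent).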
